A study of Mus musculus with 8 samples.

How the data were processed

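Expression was measured in primary mouse vascular smooth muscle cells (VSMC) of 8-week-old male C57Bl6/J mice after lentiviral delivery of short hairpin RNA against Uhrf1 (shUHRF1) or of scrambled sequence (shSCR). Per the labels, transduced cells were selected with puromycin for 2 days, and total RNA was taken at day 5, labelled with biotin and hybridised to Illumina bead arrays. The series holds 8 arrays, which are 4 RNA samples, 2 shSCR and 2 shUHRF1, each measured on 2 arrays per the series' design text. Groups were taken from the shRNA named in the labels, and sample and array numbers from the titles. The labels do not say whether the RNA samples came from separate cultures or animals, so all p-values measure only the spread between these samples, which may be technical. Whether the 2 shUHRF1 samples carry the same hairpin or different ones is also not stated in the labels, so a difference between them can be one between hairpins, cultures or RNA preparations. Arrays of 1 RNA sample are called its first and second array.

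The deposited signal of each probe is a mean bead intensity per array on a linear scale, per the file headers, with no normalization between arrays. GenomeStudio 2011.1 is named in the submitters' processing notes, and whether background was subtracted is not given in the sources used here. The deposited table also gives, per the file headers, a detection p-value for each probe and array. A further table holds the authors' processed values of the same arrays on a log2-like scale, with lumi named in the submitters' processing notes. Its log base and transform are not stated by the authors, its median was 7.86 in all 8 columns, and it served as an alternative. Deviations of each array from the mean of all arrays correlated at r = 0.969 to 0.987 across probes between that table and the normalization used here, over probes with a mean signal above 300.

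The signal table held 25671 probes and 19602 blank lines. 2 probes with unreadable entries were left out, 1 with shifted values in the second arrays and 1 with a text entry, which left 25669. Probes were named through the platform annotation. 23950 probes had 1 gene symbol, 0 had several and 1719 had none. Entrez identifiers of 23934 probes matched the mouse RefSeq table of assembly GRCm38.p6, which was used for names alone, and 0 symbols needed an update. The build behind the probe design is not given in the sources used here, so no coordinates are printed.

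Signals were background-corrected with the normexp model, with the background estimated from the detection p-values and an offset of 16, and were quantile-normalized and log2-transformed (neqc in limma 3.58.1, R 4.3.3). Figures were drawn with matplotlib. A probe was tested if its detection p was under 0.05 on all 4 arrays of at least 1 group, which kept 10880 probes for 7502 genes and 630 probes without a symbol. Each gene is represented by its tested probe with the highest mean signal. 1994 genes had several tested probes, and in 478 of these the probes differed in sign. A gene not detected on any array of 1 group has only a bound there, given as "at least N-fold" against the dimmest detected signal. A gene not detected on some arrays of a group is near background there. Its difference is printed as measured, and its size is uncertain. The number of arrays limits the precision, and between 45.1% and 48.2% of probes were detected per array.

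The 2 arrays of each RNA sample were averaged, and 2 shUHRF1 samples were compared with 2 shSCR samples by limma (lmFit and eBayes, no block) with Benjamini-Hochberg adjustment over probes at 0.05. Differences are shUHRF1 minus shSCR on the log2 scale, with the moderated standard error (SE). 18 gene lists, written before the data were examined, were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, with the tested genes as background. Camera with an estimated correlation and fry were run beside it. fry's directional p asks whether the genes of a list move one way on balance, and its mixed p whether they change in either direction. Neither compares a list with other genes. Counts of list members past the threshold are given over all genes and adjusted over the list alone.

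The lists were smooth muscle contractile genes, synthetic smooth muscle genes, DNA replication, mitosis, p53 targets and cyclin-dependent kinase inhibitors, interferon-stimulated genes, germline genes silenced by DNA methylation, imprinted genes, TGF-beta and YAP targets, extracellular matrix, DNA methylation machinery, inflammatory and senescence-associated secretory genes, osteochondrogenic markers, stress response and immediate early genes, and cholesterol synthesis. Markers of endothelial cells, of macrophages and leukocytes, and of fibroblasts were included for other cells that a smooth muscle culture could hold. Some genes belong to several lists. Genes were named by a rule also written before the data were examined. It takes Uhrf1, the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose samples do not overlap between groups, up to 4 members of each list past the threshold or else the 2 with the smallest p, and Acta2, Tagln, Myh11, Cnn1, Cdkn1a, Dnmt1, Mki67 and Spp1 where tested. Genes named outside this rule were chosen after their values were seen, and the text says so.

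The limma steps were tested on simulated data for the shUHRF1 and shSCR comparison over 10880 probes, with 50 probes changed at each size and the spread between RNA samples as measured. Averaged arrays recovered 0 of 50 probes at a log2 change of 0.5, 4 at 1, 47 at 2 and 50 at 4, and 7.34% of the calls were false. With the 8 arrays treated as separate samples, 12, 41, 50 and 50 were recovered at those sizes, and 49.0% of the calls were false. A block of shSCR samples with shUHRF1 array numbers gave 47.5% false calls, and 15.4% with the arrays of each shSCR sample averaged. The simulated data held no effect shared by the arrays of a block. These shares therefore do not give the block's error rate if such an effect exists. When the simulated RNA samples did not differ beyond their arrays, 6.70% of the calls with 8 separate arrays were false. In the simulated lists, camera called the 1 shifted list and 0 of 17 unshifted lists. The simulated genes varied independently, so this does not test lists whose genes vary together. Measured estimates of the correlation were 0.923 for mitosis, 0.768 for cholesterol synthesis, 0.698 for replication, 0.44 for contractile and -0.0348 for matrix genes.

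The alternatives chosen before the data were examined changed the background correction, the offset, the normalization between arrays, the source of the values, the filter on dim probes, the probe used for a gene, the handling of the 2 arrays of a sample, the variance model, array weights, replicate blocks, the set test and the samples left out. A slide block was not run. 5 alternatives were added after the data were seen. They are a block with crossed sample numbers, a block that joins shSCR samples with shUHRF1 array numbers, the same block with the arrays of each shSCR sample averaged, a fit with shUHRF1 sample 2 from its first array alone, and the DNA methylation machinery list without Uhrf1.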

Results

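The arrays profiled primary VSMC, the contractile cells of the vessel wall grown in culture, after RNA interference against Uhrf1, a RING-finger protein that binds hemimethylated DNA and recruits the maintenance methyltransferase Dnmt1. The comparison asks which transcripts differ between cells with shRNA against Uhrf1 and cells with scrambled shRNA. It rests on 2 RNA samples per group with 2 arrays each, and the median raw signal per array lay between 103.4 and 123.3.

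Uhrf1 itself was 6.74-fold lower in shUHRF1 cells (log2 difference -2.75, SE 0.23, n = 2 RNA samples per group, probe ILMN_2517041). Its normalized log2 signal was 11.51, 11.53, 11.45 and 11.62 on the shSCR arrays against 9.40, 8.73, 8.39 and 8.58 on the shUHRF1 arrays, so every shUHRF1 array lay below every shSCR array. Dnmt1, its partner in maintenance methylation, had a log2 difference of -0.56 (SE 0.21) and was lower on all shUHRF1 arrays. The Uhrf1 difference had the lowest adjusted p of all genes, 0.167 by limma on the averaged arrays, and did not pass the threshold there. It passed with the 8 arrays and the RNA sample as a random block, with an adjusted p of 0.00182 by limma. That fit takes 1 correlation between the arrays of a sample for all genes, here 0.192, and counts its residuals over 8 arrays. Its p-values may be too small, and it was not run on simulated data. A different Uhrf1 probe was not detected on any array.

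**Figure D1:**
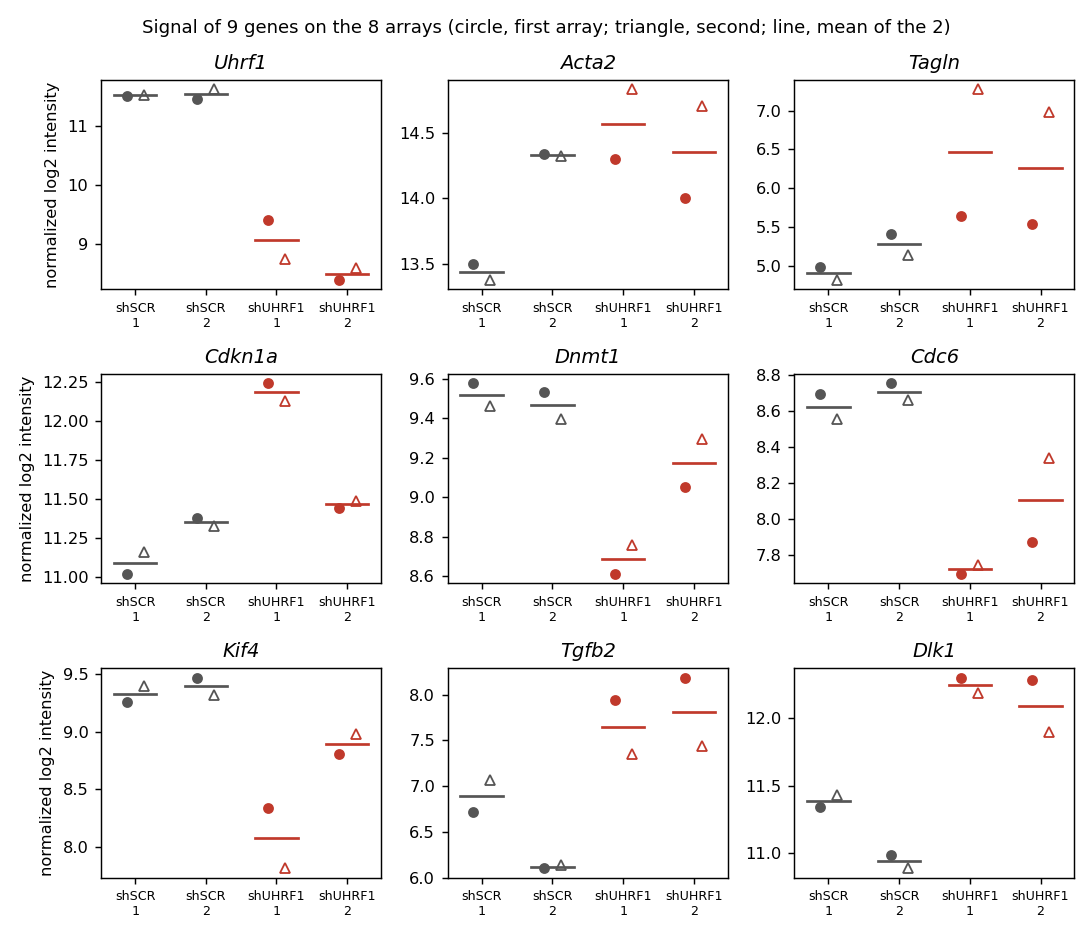
Normalized log2 intensity (vertical axes) of 9 genes on each array of the 2 shSCR samples (grey) and the 2 shUHRF1 samples (red), with circles for first arrays, open triangles for second arrays and lines for the mean of the 2 arrays. Uhrf1 lay between 11.45 and 11.62 on the shSCR arrays and between 8.39 and 9.40 on the shUHRF1 arrays, and vertical axes differ between genes and do not start at 0.

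Genes of DNA replication were lower in shUHRF1 cells almost throughout, with 37 of the 38 tested members below shSCR and a median log2 difference of -0.53. Tyms, which makes thymidylate, differed by -0.79 (SE 0.21), and Cdc6, a licensing factor of replication origins, by -0.75 (SE 0.19). All 23 tested mitosis genes were lower, with a median of -0.69, among them the phosphatase gene Cdc25c at -0.97 (SE 0.31) and the chromosome kinesin Kif4 at -0.87 (SE 0.28). In 15 replication genes and 10 mitosis genes every shUHRF1 array lay below every shSCR array. Both samples contributed in the same direction but by different amounts, since the mitosis median was -1.22 in shUHRF1 sample 1 and -0.23 in sample 2, and the replication median -0.76 and -0.25. Both lists fell as sets relative to the other genes by camera at its preset correlation, with adjusted p = 3.67e-10 for replication and 1.33e-07 for mitosis. The measured correlation between genes was far above the preset one, 0.698 for replication and 0.923 for mitosis. These p-values may therefore be far too small. With an estimated correlation camera's adjusted p was 0.536 for each list. By fry in one direction adjusted p was 0.459 for replication and 0.5 for mitosis. 0 members of either list passed limma's threshold over all genes, 0 passed adjusted over the list alone, and 17 replication and 8 mitosis genes were lower at an unadjusted p under 0.05.

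Of 21 tested p53 targets and cyclin-dependent kinase inhibitors, 19 were higher in shUHRF1 cells, with a median of 0.40. Cdkn2b, which encodes the kinase inhibitor p15, differed by 0.74 (SE 0.18), and Cdkn1a, which encodes p21, by 0.60 (SE 0.27), with 0.83 and 0.98 on its other probes. Over 25 alternatives the Cdkn1a difference ranged from 0.24 to 0.96. The kinase inhibitor genes Cdkn1b, Cdkn2a and Cdkn2c, chosen after their values were seen, stood at 0.11, 0.03 and -0.25. Plk2, a p53-induced kinase gene, was lower by contrast at -0.82 (SE 0.18). The list rose as a set by camera (adjusted p = 0.00433), with adjusted p = 0.536 with an estimated correlation, and 0 members passed limma over all genes or adjusted over the list alone, with 4 higher and 1 lower at an unadjusted p under 0.05. The median was 0.24 without shUHRF1 sample 1 and 0.13 from the second arrays alone, where camera's adjusted p was 0.0621 and 0.239.

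Smooth muscle contractile genes were higher in 11 of the 12 tested members, with a median of 0.37. 25 genes of this list had a named probe, and those not tested did not pass the detection filter. Tagln, the actin-binding protein SM22, was 2.42-fold higher (log2 difference 1.27, SE 0.20), and Csrp1, a LIM-domain protein of smooth muscle, 1.70-fold higher (0.77, SE 0.19). Tagln was dim, with a shSCR mean of 5.09 where the median of all probes was 4.7 on each array. The size of its difference is therefore uncertain. Acta2, smooth muscle alpha-actin, differed by 0.57 (SE 0.30) on its brightest probe and by 0.76, 1.13 and 1.25 on the others, and by 0.12 on the brightest without shSCR sample 1. Myh11 and Cnn1, later markers of contractile differentiation, were not detected on any array, each on its only probe. The list rose as a set by camera (adjusted p = 0.00209), with adjusted p = 0.536 with an estimated correlation. 0 members passed limma over all genes and 2, Tagln and Csrp1, rose adjusted over the list alone, beside 3 higher at an unadjusted p under 0.05. The 2 controls also differed, with a median 0.34 higher in shSCR sample 2 than in sample 1, and camera's adjusted p was 0.0654 without shSCR sample 1 (median 0.19), 0.191 from the first arrays alone (median 0.21) and 0.0596 with shUHRF1 sample 2 from its first array, a fit chosen after the data were seen. Over 25 alternatives its median ranged from 0.10, without a filter on dim probes, to 0.60, from the second arrays alone.

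Synthetic smooth muscle genes, which mark the dedifferentiated state, were also higher, in 13 of 16 tested members with a median of 0.27. Tnc, the matrix glycoprotein tenascin C, differed by 1.62 (SE 0.47), and Mmp3, a matrix metalloproteinase gene, by 1.46 (SE 0.35). The controls differed for Tnc, at 6.19 and 7.62 in shSCR samples 1 and 2, against 8.81 and 8.25 in the shUHRF1 samples. Extracellular matrix genes were higher in 23 of 28 members with a median of 0.25, and Col1a1, a chain of type I collagen, differed by 0.77 (SE 0.19) while Col1a2, its partner chain, chosen after its value was seen, differed by -0.37 (SE 0.19). Inflammatory and senescence-associated secretory genes were higher in 14 of 21 members with a median of 0.24, with the adhesion molecule gene Icam1 at 1.23 (SE 0.26). The lists rose as sets by camera, with adjusted p = 0.0354 for synthetic genes, 0.00244 for matrix and 0.0333 for secretory genes. With an estimated correlation each had camera's shared adjusted p of 0.536. The estimates were -0.0268, -0.0348 and -0.0292, below the preset 0.01, so a high correlation is not why these lists failed there. Matrix genes also moved upward on balance by fry (adjusted p = 0.0467). In each of the lists 0 members passed limma over all genes or adjusted over the list alone, with 5, 7 and 7 higher at an unadjusted p under 0.05. These lists share genes, among them Mmp3 in all of them and Tnc in the synthetic and matrix lists. Their rises are therefore not independent. The secretory list's adjusted p was 0.103 without shSCR sample 1 and 0.126 without shUHRF1 sample 2, the synthetic list's was 0.0554 without shUHRF1 sample 2, and the matrix list's was 0.0551 from the first arrays alone. For synthetic and secretory genes, adjusted p was 0.0781 and 0.0695 with median scaling, 0.0658 and 0.0505 in the authors' processed values, 0.0752 and 0.0573 without a filter on dim probes, 0.0551 and 0.21 with a stricter filter, and 0.191 for each from the first arrays alone, and for synthetic genes 0.0602 with array weights and 0.0568 with the array number as a block. The matrix median was 0.43 without shUHRF1 sample 2, and the secretory median was 0.10 without shSCR sample 1, 0.04 without a filter, 0.06 with the stricter one, 0.08 in the authors' values and 0.13 from the first arrays, and the synthetic median 0.12 without a filter and 0.09 in the authors' values.

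TGF-beta and YAP targets were higher in 15 of 18 tested members, with a median of 0.20. Ligands and a feedback regulator stood at the top, with Tgfb2 at 1.22 (SE 0.27) and Pmepa1, an inhibitor of TGF-beta signalling, at 0.85 (SE 0.19). Pmepa1 was not detected on 2 of the shSCR arrays. The list mixes ligands and receptors with target genes. Of the target genes, Ccn1, Ccn2, Amotl2 and Ankrd1, chosen after their values were seen, stood at 0.20, 0.06, 0.19 and -0.36. The list rose as a set by camera (adjusted p = 0.00706), with adjusted p = 0.536 with an estimated correlation. 0 members passed limma over all genes, and 5 were higher at an unadjusted p under 0.05. Adjusted over the list alone 4 rose, Tgfb2 and Pmepa1 and, named after their values were seen, Tgfb1 and Tgfb3. Its median was 0.46 in shUHRF1 sample 1 and 0.01 in sample 2, and camera's adjusted p was 0.378 without sample 1, 0.107 without shSCR sample 1 (median 0.06) and 0.161 from the first arrays alone. Without shSCR sample 2 the median was 0.47.

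Cholesterol synthesis genes were lower in 13 of 15 tested members, with a median of -0.47. Lss, which makes lanosterol, differed by -0.94 (SE 0.34) and Idi1, an isomerase of the mevalonate pathway, by -0.80 (SE 0.19). The list fell as a set by camera (adjusted p = 0.00244), with adjusted p = 0.595 with an estimated correlation. 0 members passed limma over all genes or adjusted over the list alone, with 2 lower at an unadjusted p under 0.05. The controls differed by more than the groups, with a median of -0.70 in shSCR sample 2 relative to sample 1, and the median was -0.20 without shSCR sample 1 (adjusted p = 0.423), -0.79 without shSCR sample 2 and -0.22 without shUHRF1 sample 1.

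Genes of the DNA methylation machinery were lower in 17 of 21 tested members, with a median of -0.21. The list holds Uhrf1, the targeted gene, whose direction the shRNA sets and which was its 1 member to fall adjusted over the list alone, while 0 passed over all genes. Cbx5, which encodes the heterochromatin protein HP1 alpha, differed by -0.69 (SE 0.17). Dnmt1 at -0.56 and Pcna at -0.19 are also in the replication list, whose median was -0.53. The falls of these lists are therefore not independent. The list fell by camera (adjusted p = 0.00528), with adjusted p = 0.536 with an estimated correlation, and by fry (adjusted p = 0.00608 for one direction, 0.0139 mixed). Without Uhrf1, a test added after the data were seen, the other 20 members had a median of -0.20 and still fell by camera (adjusted p = 0.0233, and adjusted p = 0.536 with an estimated correlation) and by fry in one direction (adjusted p = 0.0383), but not by fry's mixed test (0.24). Including Uhrf1, 4 members were lower at an unadjusted p under 0.05, and camera's adjusted p was 0.0676 from the first arrays alone.

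Germline genes silenced by DNA methylation mostly did not pass the detection filter. Only 3 of the 31 germline genes with a named probe were tested, with a median of 0.36 and camera's adjusted p = 0.271 (0.0358 without shSCR sample 2, 0.0103 without shUHRF1 sample 1, 0.988 without shSCR sample 1, and 0.828 without shUHRF1 sample 2, where the median was -0.06). Zcwpw1, a histone reader of meiosis, differed by 0.36 (SE 0.19), and Rhox5, a homeobox gene of the reproductive tract, by 0.82 (SE 0.93), with 4.62 in shUHRF1 sample 1 and 7.82 in sample 2 against 5.11 and 5.68 in shSCR. Zcwpw1 was not detected on 3 of the shSCR arrays, and Rhox5 was not detected on 2 of the shUHRF1 arrays. Imprinted genes were higher in 9 of 12 tested members, with a median of 0.16, among them the paternally expressed Dlk1 at 1.00 (SE 0.21) and the maternally expressed Igf2r at 0.84 (SE 0.23). The imprinted list rose as a set by camera (adjusted p = 0.0225), with adjusted p = 0.536 with an estimated correlation, and 0 members passed limma over all genes while 1, Dlk1, rose adjusted over the list alone, beside 4 higher at an unadjusted p under 0.05. Its median was 0.04 without shUHRF1 sample 1 (adjusted p = 0.155), 0.33 without sample 2, 0.34 without shSCR sample 1 and 0.38 without shSCR sample 2. The imprinted call was also lost without a filter on dim probes (median 0.00158, adjusted p = 0.277), with a stricter filter (0.11, adjusted p = 0.0551) and from the first arrays alone (0.28, adjusted p = 0.0676).

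Interferon-stimulated genes did not pass camera's threshold (median 0.31 over 21 members, adjusted p = 0.111), with Tap1, a peptide transporter gene, at 0.73 (SE 0.22). The chemokine gene Ccl5, not detected on any shUHRF1 array, was at least 1.38-fold lower (limma adjusted p = 0.287). The interferon median was 0.01 in shUHRF1 sample 1 and 0.47 in sample 2, and the list rose without shUHRF1 sample 1 (adjusted p = 0.0038) and without shSCR sample 1 (0.000433), but its median was -0.08 without shSCR sample 2 (adjusted p = 0.505) and 0.01 without shUHRF1 sample 2 (adjusted p = 0.998). Stress response and immediate early genes had a median of 0.12 over 25 members (adjusted p = 0.372), with Junb, a subunit of the AP-1 transcription factor, at 0.83 (SE 0.30) and Dnajb9, a chaperone of the endoplasmic reticulum, at 0.59 (SE 0.18). Of the osteochondrogenic markers only Msx2 and Sox9 were tested (0.39, SE 0.19, and 0.29, SE 0.41, adjusted p = 0.259 for the list), and camera's adjusted p for them was 0.0476 without shSCR sample 1 and 0.961 without shSCR sample 2.

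Markers of other cell types showed no shift past camera's threshold over both samples. Fibroblast markers had a median of 0.24 over 11 members (adjusted p = 0.111), with the adventitial markers Scara5 at 1.14 (SE 0.35) and Pi16 at 0.89 (SE 0.25), and the median was -0.18 in shUHRF1 sample 1 and 0.76 in sample 2. Scara5 was not detected on 2 of the shSCR arrays. Without shUHRF1 sample 1 the fibroblast list passed (adjusted p = 0.000894), as it did without shSCR sample 1 (0.0431), but not without shSCR sample 2 (0.207) or without shUHRF1 sample 2 (0.77). 5 endothelial markers had a median of 0.34 and a mean of 0.12 (adjusted p = 0.839), with Egfl7 at -0.52 (SE 0.17) and the receptor gene Flt1 at 0.65 (SE 0.29). Of the macrophage and leukocyte markers, Cd14 and Aif1 were tested, at -0.26 (SE 0.21) and 0.04 (SE 0.17), with an adjusted p of 0.699 for the list.

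**Figure D2:**
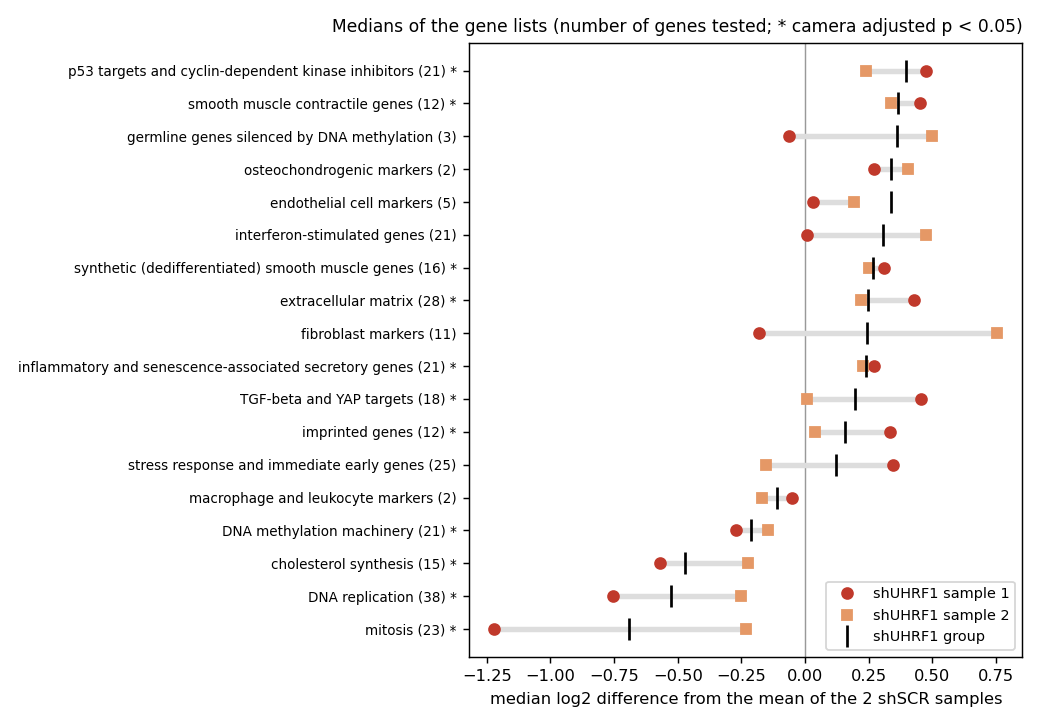
Median log2 difference from the mean of the 2 shSCR samples (horizontal axis) of the 18 gene lists, with circles for shUHRF1 sample 1, squares for sample 2 and black ticks for the shUHRF1 group, and stars beside the 11 lists past camera's adjusted threshold of 0.05. The mitosis median lay at -1.22 and -0.23 in the 2 samples, and fibroblast markers lay at -0.18 and 0.76.

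Over all genes, 0 of 7502 passed limma's adjusted threshold on the averaged arrays, while 1090 had an unadjusted p under 0.05 (593 higher, 497 lower) where 375 would be reached by chance. In 50.9% of the genes both shUHRF1 samples lay on the same side of both shSCR samples, against 33.3% by chance. Since genes vary together, how far such counts stray from 375 or 33.3% without a group effect is not known. These excesses are therefore not a test of the knockdown. In 613 genes every shUHRF1 array lay above every shSCR array and in 634 below, together 16.6% of the genes, against 2.86% by chance if all 8 arrays were exchangeable, which the arrays of 1 RNA sample are not. With the 8 arrays treated as separate samples, limma called 243 genes, 156 higher and 87 lower. These p-values are too small if the 2 arrays of a sample are technical, and 49.0% of the calls of that fit were false in simulated data with the spread between RNA samples as measured. With the RNA sample as a random block, a fit whose p-values may also be too small, limma called 3 genes.

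The genes with the largest differences among these 243, named by the same rule of size after the averaged arrays gave none, did not pass on the averaged arrays, where limma's adjusted p was 0.267 for Clu and 0.287 for the other 23. Differences and SE below are from the averaged arrays. On the higher side were the acute-phase protease inhibitor gene Serpina3n at 2.41 (SE 0.48), Rerg, a Ras-related growth inhibitor, at 1.85 (SE 0.40), the complement gene C4b at 1.79 (SE 0.34), Igdcc4 at 1.75 (SE 0.35) and Tcn2, a cobalamin carrier, at 1.65 (SE 0.33). Gpnmb, Cercam and Clu, the last encoding the secreted chaperone clusterin, stood at 1.59, 1.59 and 1.58, and Ffar4, Fndc10, Tdrp and Sprr1a at 1.41 to 1.52. Sprr1a, C4b and Rerg were not detected on 3, 2 and 1 of the shSCR arrays. On the lower side were the chemokine gene Ccl9 at -1.25 (SE 0.28), the histone gene H3c1 at -1.22, the formin gene Diaph3 at -1.10, the fatty acid elongase gene Elovl6 at -1.04 and Hirip3, a partner of the histone chaperone HIRA, at -1.03. Polr3g, Tmem144 and Ptbp3 stood at -1.03, -0.98 and -0.97, the helicase gene Blm at -0.97, the deubiquitinase gene Usp1 at -0.93, and Shmt1 and Siah1b at -0.89 each. Tmem144 and Polr3g were not detected on 3 and 1 of the shUHRF1 arrays. In the fit of 8 separate arrays their adjusted p lay between 0.00619 for Clu and 0.0492 for Gpnmb.

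The 2 arrays of a shUHRF1 sample differed from each other more than those of a shSCR sample. The standard deviation across genes of the first array minus the second was 0.49 and 0.46 in shUHRF1 samples 1 and 2 and 0.25 and 0.27 in shSCR samples 1 and 2. Deviations from the mean of all arrays were also correlated between arrays across genes. The arrays of 1 sample gave r = 0.242 and -0.000754 in shUHRF1 samples 1 and 2, and 0.572 and 0.633 in shSCR samples 1 and 2. The first arrays of the 2 shUHRF1 samples gave r = 0.373, above either shUHRF1 sample's own arrays, and the second arrays 0.000313. The second array of shUHRF1 sample 2 resembled no other shUHRF1 array (r = -0.333 to 0.000313), where those gave r = -0.254 to 0.373 with each other. Tagln, as an example, stood at 5.65 and 5.54 on the first shUHRF1 arrays and at 7.28 and 6.99 on the second, against 4.82 to 5.42 on the shSCR arrays. Acta2 stood at 14.30 and 14.00 on the first and 14.83 and 14.70 on the second shUHRF1 arrays, against 13.50 and 13.38 in shSCR sample 1 and 14.34 and 14.32 in sample 2.

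**Figure D3:**
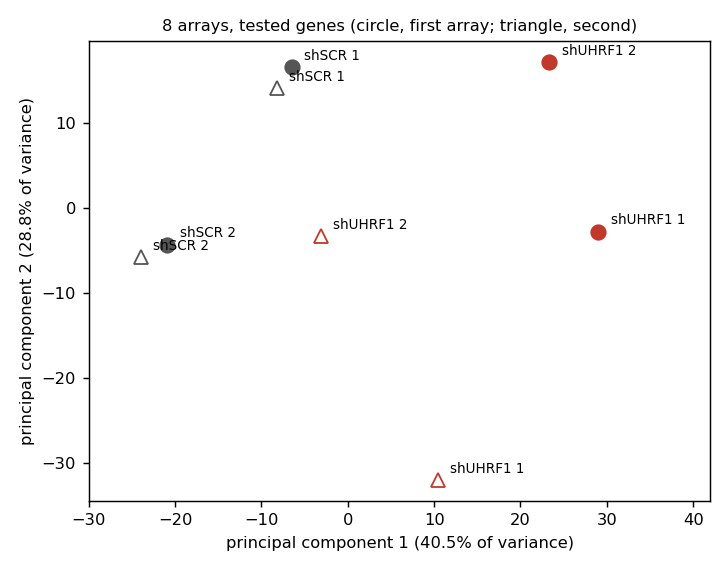
Scores of the 8 arrays on the first principal components of the tested genes (horizontal axis, component 1 with 40.5% of the variance, and vertical axis, component 2 with 28.8%), with shSCR in grey, shUHRF1 in red, circles for first and open triangles for second arrays. The arrays of each shSCR sample lie close together, and the arrays of each shUHRF1 sample lie apart. The second array of shUHRF1 sample 2 lies at -3.12 on component 1, on the side of the shSCR arrays, and the other shUHRF1 arrays at 10.4 to 29.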

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

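The tests in this part that compare array differences, Uhrf1 levels, normalizations, contractile medians and cell type markers, and the fits with letters as a block, were chosen after the results were seen, and the count over splits of the arrays was planned. In 6 of 126 groups of 4 arrays examined, 1 array stood far from the other 3, where chance gives about 1 in 20 groups, or 6.3. The matrix metalloproteinase gene Mmp3 stood at 7.05 on the first array of shUHRF1 sample 1 and at 9.11 to 9.51 on the other shUHRF1 arrays. The formin gene Diaph3 stood at 8.93 on the second array of shUHRF1 sample 2, against 7.99 to 8.10. The chaperone gene Dnajb9 stood at 9.33 on the second array of shUHRF1 sample 1, against 8.62 to 8.73. In shSCR, Cercam stood at 8.03 on the first array of sample 1, against 7.64 to 7.65, and Igdcc4 at 5.32 on its second array, against 5.20 to 5.22. The median raw signal was 103.4 on the first array of shSCR sample 2, against 115.1 to 116.8 on the other shSCR arrays.

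Genes such as Tagln and Acta2 differed between the first and second shUHRF1 arrays in the same way in both samples. Independent array noise is argued against, since across genes these differences correlated between the 2 shUHRF1 samples at r = 0.569, against 0.168 between the shSCR samples. A batch of all first or all second arrays is also argued against, since the shSCR differences followed the shUHRF1 differences with a slope of 0.112 at most. What stays open is that the array letters of shUHRF1 may mark the same cultures, animals or days as shSCR samples 1 and 2, because shSCR sample 1 minus sample 2 correlated with first minus second shUHRF1 arrays at r = 0.392 or more in every pairing of single arrays. With shSCR sample 1 joined to the first and sample 2 to the second shUHRF1 arrays as a block, limma called 903 genes, 538 higher and 365 lower. This counts the repeat arrays of a shSCR sample as separate, and 0 genes were called with these averaged. In simulated data with the spread between RNA samples as measured, 47.5% of the block's calls were false. Those data held no effect shared by array letters, so they do not give the error rate if the letters mark a common origin. The block is also a hypothesis tested on the data that raised it.

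Replication and mitosis genes lay further below shSCR in shUHRF1 sample 1 than in sample 2. The normalization is argued against, since under every other normalization the difference kept its sign and at least 0.548 of its size. A deeper knockdown in sample 1 would need Uhrf1 to be lower there, and it was higher, by 1.01 on the first arrays and 0.153 on the second (9.07 against 8.48 on average). That explanation is left open rather than excluded because 0.153 is within the 0.169 by which the arrays of a shSCR sample differed and the mean difference did not pass limma (-0.58 for sample 2 minus sample 1, SE 0.20, adjusted p = 0.123), and this bound was made stricter after 0.153 was seen, where the earlier bound, higher on both array sets, would have excluded it. No biological explanation was tested.

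Contractile genes such as Tagln and Csrp1 were higher in shUHRF1 cells. An uneven origin of the shSCR samples is left open, since with the shUHRF1 arrays set against the shSCR sample of the same letter the median was 0.235 and 0.474, and 0.235 is within the 0.335 by which the 2 shSCR samples differed, a bound set after these values were seen, where the earlier bound, the difference between arrays of a shSCR sample, would have excluded it but is technical spread alone. With the letters as a block the list passed camera (adjusted p = 0.000449, and 0.00054 with the arrays of each shSCR sample averaged), which does not decide, because that block is balanced between the groups and leaves every difference as it was (median 0.365). A loss of fibroblasts cannot be told apart over both samples. In shUHRF1 sample 1 the contractile median was 0.451 and the fibroblast median -0.182. In sample 2 they were 0.336 and 0.755, so fibroblast markers were higher there, not lower, in that 1 RNA sample. An effect of the knockdown on smooth muscle differentiation, the contrast of the design, may contribute and stays a hypothesis.

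Treating the arrays as separate samples, 1 of the 35 splits of the 8 arrays into groups of 4, the real one, gave as many as 243 genes. The planned bound, a share of these splits under 0.05, holds only for arrays that are exchangeable, which those of 1 RNA sample are not, so it is not used. Only 3 splits keep the RNA samples whole, too few for a share under 0.05, and the highest other of them gave 0 genes. The highest other of all splits gave 85 genes and set shSCR sample 1 with the first shUHRF1 arrays against the rest, which points to a structure of the samples, and the remaining 33 gave 0.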

How the results depend on the processing

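The letter block with and without averaged shSCR arrays, the crossed numbers, the list without Uhrf1 and the fit with shUHRF1 sample 2 from its first array were chosen after the data were seen. Uhrf1 was lower in all 25 alternative fits. Its difference of -2.75 passed the threshold with 8 arrays and the RNA sample as a random block (3 genes called), with 8 arrays as independent (243 genes), with a variance trend (1 gene), with a robust trend (1 gene), with array weights (-2.75, 2 genes), and from the second arrays alone (-2.92, 1 gene). Title numbers gave no pairing, since same-numbered samples deviated with r = -0.161. A replicate block on the title number gave -2.75 for Uhrf1 and 1 gene, a replicate block on the array number -2.75 and 2 genes, crossed title numbers -2.75, 2 genes and 12 lists, now with interferon genes, and the letter block -2.75 and 903 genes, or 0 genes and the same 11 lists with the arrays of each shSCR sample averaged. Leaving out 1 RNA sample, where the lone sample is assumed to vary like the other group, gave -3.04 to -2.46 for Uhrf1, 0 genes and 9 to 12 lists. From the first arrays alone 5 lists passed, 4 of the 11 and the interferon list. On the averaged arrays 0 lists passed with an estimated correlation and 2 with fry. The replicate block on the array number ended only the call of synthetic genes (camera's adjusted p = 0.0568). With shUHRF1 sample 2 from its first array, 9 lists passed, without contractile (median 0.225, adjusted p = 0.0596), synthetic (0.0773) and secretory genes (0.0625) and with interferon genes (0.0485). Synthetic and secretory genes passed in 16 and 17 of 25 alternatives. Replication and mitosis passed in all 25 alternatives that keep camera's preset correlation. On the averaged arrays neither passed with an estimated correlation or with fry. Results that reversed were uncalled. From the first arrays alone Flt1 was -0.01, Aif1 -0.19 and the endothelial median -0.00795. From the second arrays alone Cd14 was 0.052, Sox9 -0.13, the interferon median -0.034 and the leukocyte median 0.16. Without a filter the germline median was -0.0225 and the endothelial median 0.0102, and that list's test changed sign at a median of 0.338 with the random block and with the replicate block on the array number. Leaving out 1 sample gave -0.038 to 0.11 for Aif1, -0.38 to 0.96 for Sox9, -0.78 to 2.42 for Rhox5, 0.23 to 1.08 for Flt1, -0.49 to -0.027 for Cd14, and medians of 0.0299 to 0.231 for endothelial (0.338 with all samples), -0.0783 to 0.587 for interferon, -0.264 to 0.0428 for leukocyte, 0.0111 to 0.665 for osteochondrogenic, -0.155 to 0.346 for stress, -0.0637 to 0.664 for germline and -0.182 to 0.755 for fibroblast genes. The causes were not tested. The germline list could not be tested under the strict filter, and a slide block was not run, since the files used here give no slide. Signal over background limits dim genes such as Tagln.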

Other observations

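All comparisons in this part were chosen after the data were seen. The 2 shUHRF1 samples differed from each other in genes that the group comparison averages away. Rhox5, a homeobox gene of the reproductive tract that DNA methylation silences in somatic cells, stood at 7.59 and 8.04 on the arrays of shUHRF1 sample 2, at 4.69 and 4.55 in sample 1 and at 5.05 to 5.82 in shSCR. Ifi27l2a, an interferon-stimulated gene, stood at 8.86 in sample 2, 5.12 in sample 1, and 7.54 and 6.41 in shSCR. Actg2, smooth muscle gamma-actin, stood at 9.57 in sample 2 and 6.48 in sample 1, against 5.47 and 6.71 in shSCR, and Nt5e, the ectonucleotidase CD73, at 10.01 and 7.85, against 8.60 and 9.34. Cdkn1a was higher in sample 1, at 12.19 against 11.46 in sample 2, with 11.09 and 11.35 in shSCR. In a limma model with both groups and the array letters as terms, 340 genes were higher and 230 lower in sample 2 than in sample 1 over the 8 arrays. That test compares 2 RNA samples by the spread of their arrays and says nothing about other samples.

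With the letter block, further genes entered the largest differences by the same rule of size, and some of them varied with the letters. The collagenase gene Mmp13 was at 2.27, the angiopoietin gene Angpt2 at 2.24, the glycogen-targeting subunit gene Ppp1r3c at 1.81 and Tnc at 1.62, beside Serpina3n at 2.41. Among the lowest were the histone genes H3c1 and H3c6 at -1.22 and -1.14, the sulfotransferase gene Chst1 at -1.18, and Depdc1b, a cell cycle gene, at -1.14. Several of these depend on which control is used, since shSCR samples 1 and 2 stood at 5.36 and 7.80 for Mmp13, 8.78 and 6.14 for Angpt2, 7.57 and 5.53 for Ppp1r3c and 6.19 and 7.62 for Tnc. All 243 genes called with the arrays as separate samples were among the 903 called with this block, and 0 genes were called with the block when the arrays of each shSCR sample were averaged.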
